A study of Homo sapiens with 6 samples.

How the data were processed

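Gene expression was measured by RNA-seq in HK2 cells, in 3 DMSO and 3 TBOEP libraries grouped by the treatment label of each sample. Per the labels' protocols, total RNA was extracted with TRIzol and its integrity was measured on a Bioanalyzer, with a minimum integrity number for further work. The labels name 2 library kits, a VAHTS Universal V6 kit and a TruSeq Stranded Total kit, and do not say which libraries were made with which, so whether counting used strand is not known. Trimmomatic and HISAT2 are named in the submitters' processing notes, without versions. The counting tool, the genome build and the annotation are not given in the sources used here, so no coordinates are printed.

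The deposited table gave 1 value per gene and library for 25808 Ensembl gene IDs, with no unit in its header. The unit was inferred as FPKM from the values: in each gene the 6 deposited FPKM values were whole multiples of 1 step once each library had 1 factor. Whole reads were recovered for 25808 genes within a tolerance of 0.01 reads, and the implied lengths of 2568 of 11786 genes with over 300 reads equalled the merged exon length of GENCODE 29. Recovery was tested on simulated data, where it returned 99.64% of simulated genes with over 300 reads exactly; that share was not computed for genes with fewer reads, such as CYP1A1 and PCK1, whose reads are less certain. Gene names came from a table of Ensembl IDs and matched 25795 IDs. Where a symbol occurred in several rows, the row with the highest mean stood for it in the lists.

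Because the values were FPKM, the test fixed for that case before the data were examined was used: limma 3.58.1 in R 4.3.3, with a trended and robust empirical Bayes fit on log2(FPKM + 1), for genes at 1 FPKM or more in at least 3 of 6 libraries, and Benjamini-Hochberg adjustment over 9631 genes. Each test was two-sided and had no covariate. Gene lists, 42 in all and fixed before the data were examined, were tested by camera with an inter-gene correlation of 0.01 where at least 5 members were tested, which left 34 lists adjusted together. The other 8 lists, gluconeogenesis and markers of 7 other cell types, had fewer tested members: 2 for gluconeogenesis, 3 for podocyte (NES, CDKN1C, SYNPO), 1 each for endothelium (EGFL7), fibroblast (COL1A1), leukocyte (CSF1R) and neuron (GAD1), and 0 for loop of Henle and distal tubule and for collecting duct. Genes are named by a rule fixed at the same time: the 8 largest rises and 8 largest falls among called genes with a mean of at least 1 FPKM, a symbol and no overlap between groups; up to 4 members with the smallest p of each list described; and 12 genes always given. Some genes that this rule takes are not reported here.

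The test was run on simulated data in 20 simulations of 9631 genes, with reads drawn from the DMSO means and library sizes and 200 genes changed by known folds. It recovered 78.2% of genes changed 1.25-fold, 94.2% at 1.5-fold, 95.3% at 2-fold and 97.4% at 3-fold, and called a list shifted by 0.3 in all 20. Of the calls, 7.36% on average (4.63% to 13.2%) fell on unchanged genes, above the 5% that the threshold allows for, although 4.89% of unchanged genes had an unadjusted p under 0.05. A limit set on 1 simulation before this, that fewer than 10% of calls be on unchanged genes, was missed; the test was kept as fixed and the share measured over 20 simulations in its place. Without robust moderation the share was 6.3%. The simulation assumes 1 dispersion for all genes, draws genes independently and has no GC or length trend. It changes only the 200 genes and the 22 of the shifted list, whereas 53.8% of tested genes were called in the real data. The recovery and the share on unchanged genes may therefore differ there. Independent genes cannot test the inter-gene correlation that camera assumes. Over all simulations, camera made 2 calls of lists other than the shifted one.

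Replicates were compared by a chi-square of the recovered reads. All 6 pairs within groups differed by more than sampling noise, with a chi-square of 8.91 to 13.5 per degree of freedom, so none was counted as 1 library. The alternatives fixed beforehand were limma without trend, quantile normalization, median centring, no filter, a filter at 5 FPKM, a pseudocount of 0.1, the replicate number as a block, each library left out, and camera with an estimated correlation, camera on ranks and fry. Added after the data were seen were limma-voom on the recovered reads, protein-coding genes alone, limma without robust moderation, and a GC and length correction. That correction used mgcv 1.9.3 to fit, in each library, a smooth surface of GC content and log length to the deviations from each gene's mean, and subtracted it. GC content and length came from 1 transcript per gene in GENCODE 29 and were known for 98.9% of tested genes.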

Results

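RNA from HK2 cells, an immortalised line of human kidney proximal tubule cells, was profiled by RNA-seq in 6 libraries. In 3 libraries the cells had been given 20 µM tris(2-butoxyethyl) phosphate (TBOEP), an organophosphate ester used as a flame retardant and plasticiser, for 48 hours, and 3 libraries came from cells given the solvent DMSO, whose dose and time the labels do not state. The deposited values were FPKM per gene. The library totals behind the FPKM, recovered from the steps between values, came to 38247579, 33536445 and 36093609 in DMSO replicates 1 to 3 and to 35838657, 34890085 and 32547856 reads in TBOEP replicates 1 to 3. At these depths 1 read on a transcript of 1 kb was worth between 0.0261 and 0.0307 FPKM. The labels do not say whether replicates were separate cultures, so the p-values below measure only the spread between these libraries, which may be technical.

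The comparison of TBOEP with DMSO addressed how the compound bears on renal metabolism. TBOEP-treated cells held about 3 times the level of several abundant mRNAs. ANXA2 (ENSG00000182718), a calcium-dependent membrane-binding protein, rose from 44.5 ± 0.793 to 143 ± 0.581 FPKM (mean ± SD, n = 3 per group). CCT3 (ENSG00000163468), a subunit of the CCT chaperonin that folds actin and tubulin, rose from 49.2 ± 0.518 to 148 ± 1.43 FPKM. PGK1 (ENSG00000102144), a glycolytic enzyme, rose from 206 ± 2.1 to 556 ± 4.69 FPKM. On the log2(FPKM + 1) scale the largest fall was in RMRP (ENSG00000277027), the RNA of the RNase MRP complex, at 19.4 ± 9.69 FPKM in DMSO and 1.98 ± 1.77 FPKM in TBOEP.

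By limma on log2(FPKM + 1) with Benjamini-Hochberg adjustment, 5178 of 9631 tested genes changed at an adjusted p under 0.05, 2592 up and 2586 down. On this scale, which understates the change of low genes, most changes were small: 4255 of the called genes, or 82.2%, had an absolute log2 fold change under 0.5, and the median over called genes was 0.30. A change of at least 2-fold was called for 82 genes, 73 up and 9 down. The 3 TBOEP and 3 DMSO libraries did not overlap in 62.3% of tested genes, where chance gives 10%. Centring each library on its median changed the split of called genes from 50.1% up to 38.6% up. The count of 2-fold changes was 165 with a pseudocount of 0.1, 209 with limma-voom on the recovered reads and 34 after a correction for GC content and transcript length, the last 2 chosen after the data were seen. The 9 falls became 5 without TBOEP replicate 2, 19 with a pseudocount of 0.1, 37 with limma-voom, 16 without robust moderation, 6 after the correction and 2 among protein-coding genes alone.

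ACAT2, a cytosolic enzyme of acetyl-CoA use in cholesterol synthesis, rose by 1.51 ± 0.04 on the log2 scale (SE; limma adjusted p = 2.83e-08). HADHB, the beta subunit of the mitochondrial trifunctional protein of fatty acid oxidation, rose by 1.48 ± 0.07 (limma adjusted p = 1.34e-06). IFT52, part of the intraflagellar transport complex of cilia, rose from 5.09 ± 0.0698 to 15.8 ± 0.353 FPKM, and DRG1, a GTP-binding protein, from 18.2 ± 1.34 to 50.5 ± 1.39 FPKM (n = 3 per group). The largest rise of all was assigned to ANXA2P2, a processed pseudogene of ANXA2, at 1.71 ± 0.06. Its sequence is close to that of ANXA2 and reads may be shared between them, so its value is uncertain, and so is that of ANXA2 given above.

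Among the 8 largest falls, SPATC1L fell from 2.65 ± 0.905 FPKM to between 0 and 0.0246 FPKM in the 3 TBOEP libraries (limma log2 fold change -1.83 ± 0.16, adjusted p = 5.59e-05). With limma-voom it was at -7.92, a size that depends on the prior count because 2 TBOEP libraries are at 0. RPS29, a protein of the small ribosomal subunit, fell from 125 ± 6.58 to 60.5 ± 6.26 FPKM, and the short non-coding RNA BCYRN1 from 19.5 ± 1.71 to 8.83 ± 1.02 FPKM (n = 3 per group). The snoRNA SNORD104 fell by 1.03 on the log2 scale and the microRNA gene MIR429 by 1.21. The pseudogenes RPL37AP1 and FAM27B fell by 1.33 and 1.12, and both are uncertain for reads shared with related genes. Many of these falls were in short transcripts, of 70 bases for SNORD104, 83 for MIR429, 200 for BCYRN1 and 264 for RMRP. RPL37AP1 and FAM27B have 279 and 213 bases. Tested genes under 500 bases had a median log2 fold change of -0.14. Whether the libraries measured such short RNAs reliably was not tested. The limma call of RMRP ended without DMSO replicate 2 or 3 or TBOEP replicate 2 or 3 (adjusted p 0.0517 to 0.0633), that of MIR429 without DMSO replicate 1 or any 1 TBOEP replicate (0.0807 to 0.0963). That of SNORD104 ended without DMSO replicate 2 or TBOEP replicate 2 (0.0581 and 0.0554). MIR429 was also not called after the GC and length correction (adjusted p = 0.1).

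**Figure D1:**
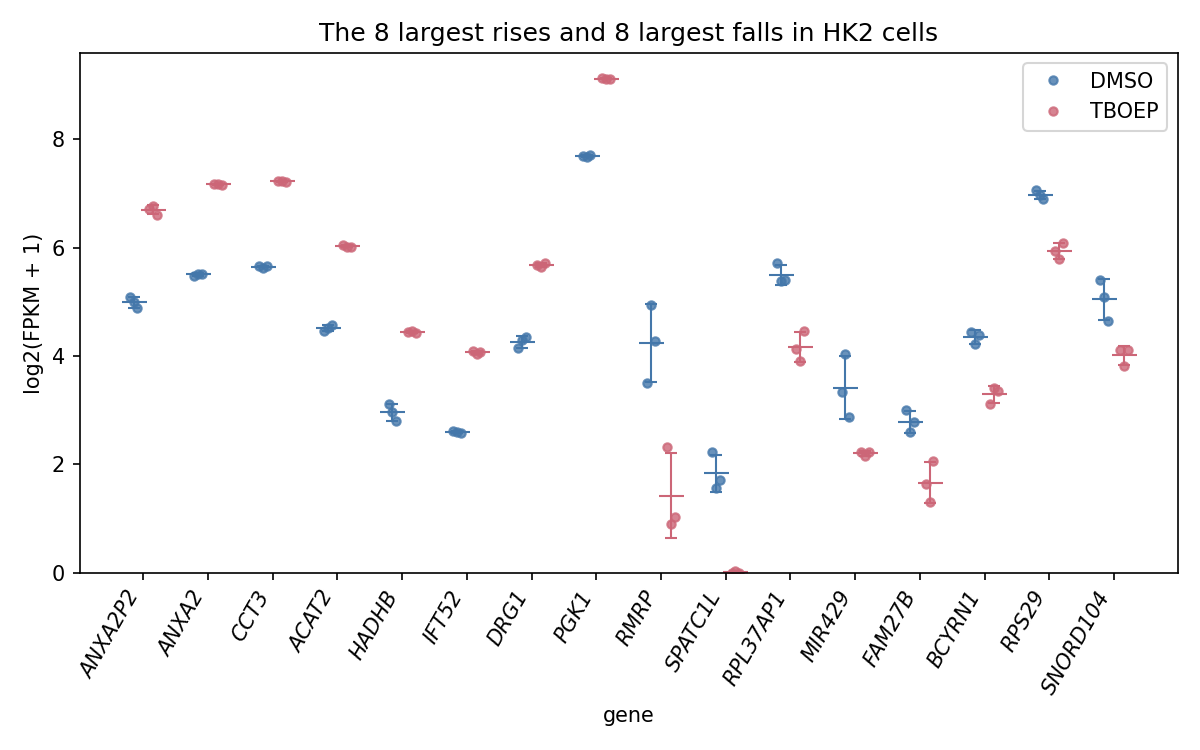
Expression of the 8 genes with the largest rises and the 8 with the largest falls, as log2(FPKM + 1) on the vertical axis, with 1 point per library, DMSO in blue and TBOEP in red; horizontal marks and bars are the mean and SD of 3 libraries. The groups do not overlap in any of these genes, which the rule that chose them required. RMRP has the widest spread, at 19.4 ± 9.69 FPKM in DMSO.

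Genes induced in hypoxia or by HIF rose as a group. Of 23 measured members, 19 rose, 0 fell and 4 did not pass, and 20 rose when adjusted over the list alone. PGK1 rose by 1.43, BNIP3, a mitochondrial protein of mitophagy, by 0.83 ± 0.03, NDRG1 by 0.73 ± 0.05 and P4HA2, a collagen prolyl hydroxylase, by 0.61 ± 0.04 on the log2 scale. The list was called by camera on the log2(FPKM + 1) values (adjusted p = 1.15e-05), and adjusted p = 0.257 with an estimated correlation.

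Glycolysis genes, a list that shares PGK1, ENO2, SLC2A1, PFKFB3 and PFKFB4 with the hypoxia list and so is not independent of it, also rose: 14 of 20 measured members rose, 3 fell and 3 did not pass, and 15 rose when adjusted over the list alone. PGAM1 rose from 549 ± 2.15 to 877 ± 4.72 FPKM, ENO1 from 1320 ± 11.2 to 1850 ± 5.51 FPKM (0.49 on the log2 scale, and 0.76 after quantile normalization) and ENO2 from 53.1 ± 0.18 to 70.4 ± 1.31 FPKM (n = 3 per group). The camera adjusted p was 0.00177, and adjusted p = 0.332 with an estimated correlation.

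Of 22 measured genes of the TCA cycle and pyruvate oxidation, 12 rose, 1 fell and 9 did not pass, with the same counts when adjusted over the list alone. SUCLG1, a subunit of succinyl-CoA ligase, rose by 1.38 ± 0.05 on the log2 scale, PDHB and PDHA1, subunits of pyruvate dehydrogenase, by 1.10 ± 0.06 and 0.70 ± 0.04, and the malate dehydrogenase MDH1 by 0.53 ± 0.04. The list was called by camera on the log2(FPKM + 1) values (adjusted p = 0.00148), and adjusted p = 0.257 with an estimated correlation.

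The mRNAs encoded by mitochondrial DNA moved the other way: 0 of 13 rose, 11 fell and 2 did not pass, and 12 fell when adjusted over the list alone. MT-CYB fell from 2260 ± 84.7 to 1770 ± 56.5 FPKM and MT-ND5 from 856 ± 27.5 to 664 ± 33.4 FPKM, while MT-ND3 fell by 0.39 and MT-ND6 by 0.48 on the log2 scale. The camera adjusted p was 0.00148, and adjusted p = 0.626 with an estimated correlation. After quantile normalization neither the list (adjusted p = 0.179) nor MT-CYB (limma adjusted p = 0.0681) was called. The list's median was then -0.14 in place of -0.29, and MT-ND3 was at -0.11. Of 47 nuclear genes of oxidative phosphorylation, 14 rose, 23 fell and 10 did not pass, and the list was not called by camera (adjusted p = 0.46), with a median of -0.08 and a mean of 0.00. The ATP synthase subunits ATP5F1B and ATP5F1A rose by 0.93 and 1.03, and UQCRFS1, of complex III, by 0.73.

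Of 23 autophagy and lysosome genes, 14 rose, 0 fell and 9 did not pass, with the same counts when adjusted over the list alone. NPC2, a lysosomal cholesterol carrier, rose from 77.5 ± 0.847 to 176 ± 1.5 FPKM, the alpha-galactosidase GLA from 4.11 ± 0.147 to 12.3 ± 0.697 FPKM and the protease CTSL from 7.78 ± 0.546 to 16.6 ± 0.787 FPKM. WIPI1, an autophagosome protein, rose by 0.85 ± 0.05 on the log2 scale. The camera adjusted p was 0.00536, and adjusted p = 0.422 with an estimated correlation. With a filter at 5 FPKM it was 0.0934.

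Of 23 genes of the pentose phosphate pathway and nucleotide synthesis, 13 rose, 3 fell and 7 did not pass, with the same counts when adjusted over the list alone. PRPS1, which makes the ribose phosphate donor of nucleotides, rose by 1.35 ± 0.03 on the log2 scale, UMPS of pyrimidine synthesis by 0.96 ± 0.06, and TALDO1 and PGD by 0.48 and 0.39. The camera adjusted p was 0.0241, and adjusted p = 0.422 with an estimated correlation. After the GC and length correction it was 0.134, with the median of the list at 0.07 in place of 0.22.

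**Figure D2:**
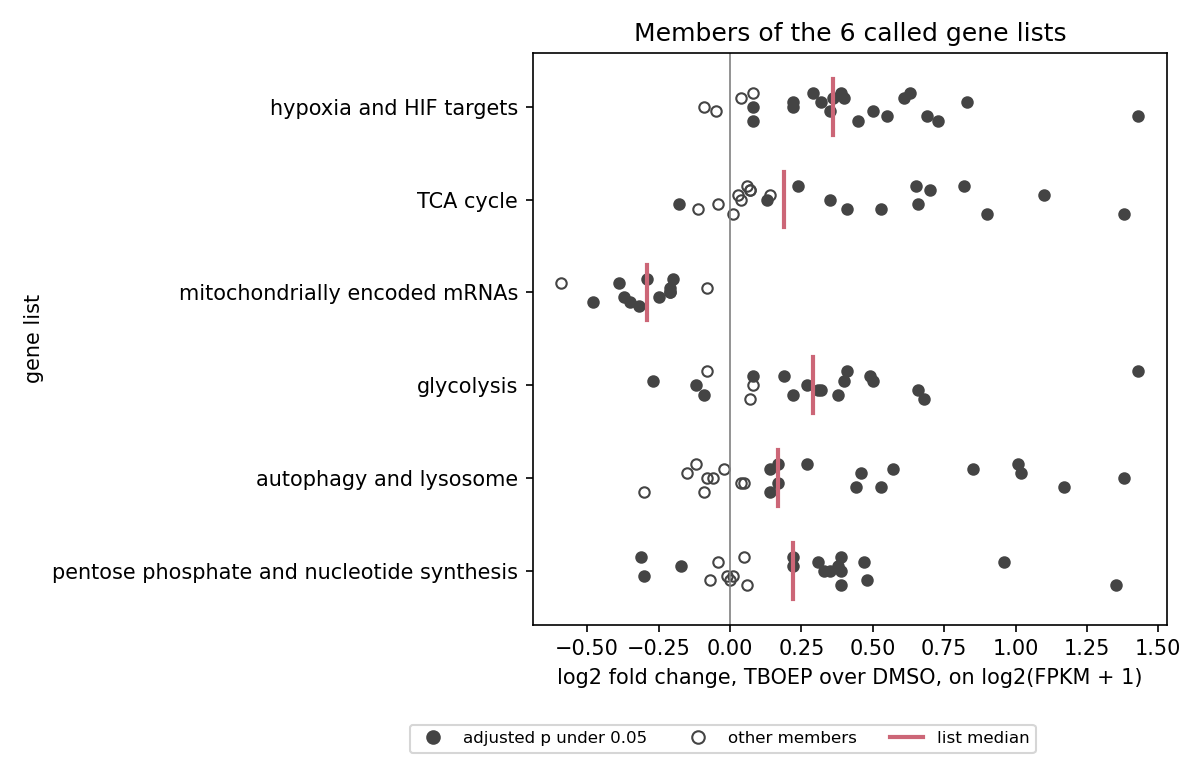
Log2 fold change (TBOEP over DMSO, on log2(FPKM + 1)) of each measured member of the 6 called gene lists, filled where the limma adjusted p was under 0.05 and open otherwise; red lines mark list medians. The medians run from -0.29 for mitochondrially encoded mRNAs to 0.36 for hypoxia and HIF targets, and the vertical spread of points has no meaning.

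Other metabolic lists held large changes in single genes without being called. In fatty acid oxidation, 8 of 19 measured members rose and 4 fell, also when adjusted over the list alone, and the camera adjusted p was 0.373. HADHA rose by 0.77 ± 0.04 and ECI2 by 0.84 ± 0.06 on the log2 scale. ECI1 fell by 0.57. In cholesterol synthesis and uptake, 9 of 22 rose and 4 fell, also when adjusted over the list alone, and the camera adjusted p was 0.373, or 0.0479 with no filter on low values. HSD17B7 rose by 0.97 (1.75 with limma-voom) and INSIG1 by 0.47. HMGCS1 differed by 0.13 ± 0.06 (limma adjusted p = 0.119). CPT1A, which joins fatty acids to carnitine for their entry into mitochondria, differed by -0.19 ± 0.08 (limma adjusted p = 0.0901). CPT1A was called lower by limma in 4 alternatives: without DMSO replicate 2 (adjusted p = 0.0282), with libraries centred on their medians (0.0321), with limma-voom (0.0355) and after the GC and length correction (0.0293).

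Stress lists were not called either. In the NRF2 and glutathione list, 9 of 16 measured members rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.123). The list was called after quantile normalization (0.0412) and with no filter on low values (0.00464). NQO1 rose from 45.1 ± 2.12 to 87.9 ± 2.41 FPKM and the ferritin light chain FTL fell by 0.35 on the log2 scale, at -0.16 and not called after quantile normalization (limma adjusted p = 0.0803). NFE2L2, which encodes NRF2, differed by -0.12 ± 0.06 (limma adjusted p = 0.0978) and was called lower in 4 alternatives, from -0.12 in limma without trend (0.0438) to -0.40 after the GC and length correction (4.66e-04). In the ER stress and ATF4 list, 11 of 23 rose and 4 fell, with 11 and 6 when adjusted over the list alone (camera adjusted p = 0.373). DDIT3 rose by 1.14 ± 0.07, XBP1 by 0.62, and DDIT4 and PDIA6 by 0.45 each, PDIA6 not after the GC and length correction (limma adjusted p = 0.0832). ATF3 rose by 0.35 ± 0.07 (limma adjusted p = 0.00298), a call that ended after the GC and length correction (log2 fold change 0.00).

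Kidney injury markers were not called as a group: 4 of 18 measured members rose and 5 fell, also when adjusted over the list alone, and the camera adjusted p was 0.863. HAVCR1, which encodes KIM-1, stood at 17.8 ± 0.517 FPKM in DMSO and 17.3 ± 1.29 FPKM in TBOEP (limma adjusted p = 0.568), and LCN2, which encodes NGAL, at 11.2 ± 0.618 and 11.3 ± 0.795 FPKM (limma adjusted p = 0.926). B2M, VIM and SPP1 rose by 0.43, 0.34 and 0.25 on the log2 scale, and CDKN1A fell by 0.36. After the GC and length correction HAVCR1 was called lower, at -0.42 (limma adjusted p = 4.21e-04). In the matrix, fibrosis and mesenchymal list, 6 of 24 rose and 12 fell, also when adjusted over the list alone (camera adjusted p = 0.39). TGFBI rose by 0.27, while TAGLN and THBS1 fell by 0.41 and 0.42.

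Proximal tubule identity genes were mostly low in this line, and 5 of the 22 listed were tested, of which 0 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.373). MIOX fell from 19.9 ± 0.711 to 14.9 ± 1.6 FPKM and CDH6 from 4.41 ± 0.0376 to 3.79 ± 0.104 FPKM, calls that ended after the GC and length correction; that of CDH6 also ended without TBOEP replicate 2 (limma adjusted p = 0.0521). PAX8 stood at 37.1 ± 1.43 and 36.7 ± 0.204 FPKM (limma adjusted p = 0.752), and ALPL at 1.77 ± 0.269 and 1.39 ± 0.148 FPKM (limma adjusted p = 0.0703; 0.0252 without DMSO replicate 3, 0.0282 with median centring and 0.04 among protein-coding genes alone). PPARA (0.579 ± 0.0833 FPKM in DMSO, 0.645 ± 0.0458 in TBOEP) and PPARGC1A (0.502 ± 0.153 and 0.314 ± 0.0601) were below the filter and were not tested. CYP1A1 had at most 12 reads in any library and PCK1 at most 2.

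Fold changes followed GC content and transcript length across genes. Genes with 45 to 50% GC had a median log2 fold change of 0.16 and genes above 60% GC one of -0.23; 64.4% of the latter fell and 1.32% rose. GC content and length together accounted for 34.2% of the variance of fold changes across genes, which are not independent replicates. The other 9 splits of the libraries, which part the groups incompletely, gave 13.2 to 24.9%. Of the 73 genes that rose at least 2-fold, 55 had 42 to 54% GC and 1000 to 3000 bases, a range that held 17.7% of tested genes with known GC content. After the correction the median of the hypoxia list went from 0.36 to 0.30, of glycolysis from 0.29 to 0.22, of the TCA cycle from 0.19 to 0.12, of autophagy and lysosome from 0.17 to 0.09 and of mitochondrially encoded mRNAs from -0.29 to -0.46. These 5 lists were still called by camera, the TCA cycle at an adjusted p of 0.0291 and autophagy and lysosome at 0.0195. With an estimated correlation on the corrected values none of the 5 was called. The adjusted p was 0.152 for hypoxia and for glycolysis, 0.268 for the TCA cycle and for autophagy and lysosome, and 0.474 for mitochondrially encoded mRNAs. The YAP and TEAD targets (adjusted p = 0.0269, median -0.20) and the cytosolic ribosomal proteins (0.0495, median -0.22) were called lower by camera after the correction and not before it, with adjusted p = 0.268 and 0.499 with an estimated correlation. Among named genes that were still called after the correction, the log2 fold change shrank by over 1.5 times to 0.43 in PGAM1, 0.25 in ENO2, 0.39 in P4HA2, 0.15 in PGD, 0.45 in WIPI1, 0.22 in INSIG1 and 0.61 in ATP5F1B. It also shrank to 0.18 in MDH1, 0.50 in HADHA, 0.48 in ECI2, 0.26 in XBP1, 0.15 in VIM, 0.09 in SPP1, 0.07 in TGFBI and -0.33 in ECI1. It grew by over 1.5 times to -0.64 in MT-CYB and -0.70 in MT-ND5.

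**Figure D3:**
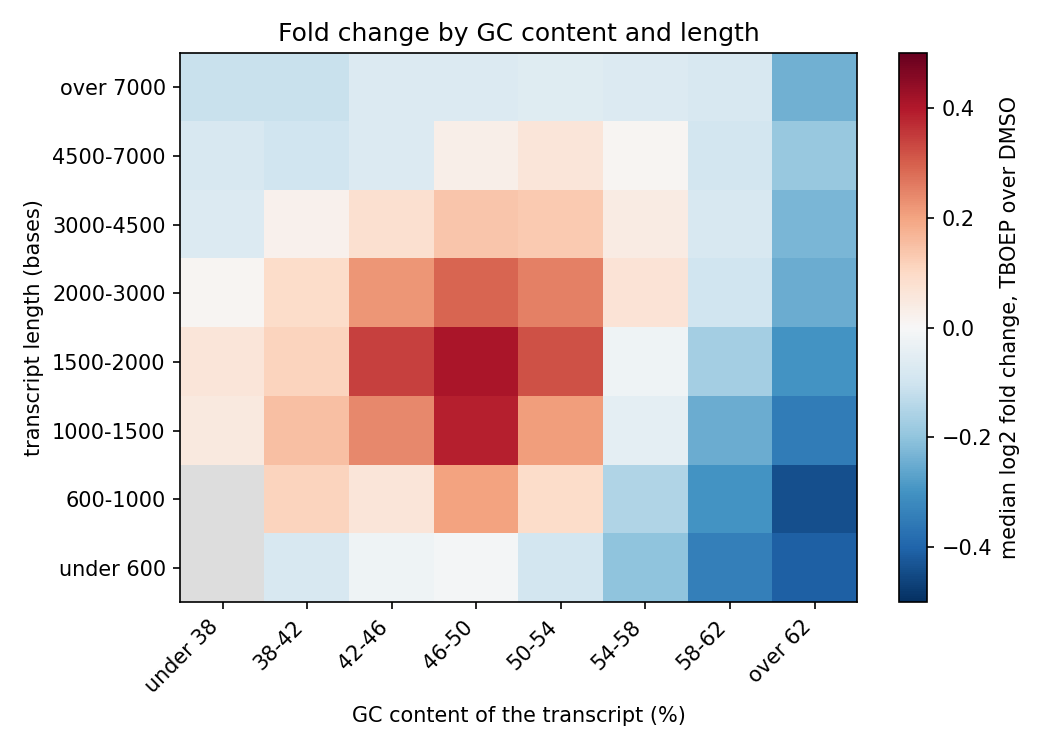
Median log2 fold change (TBOEP over DMSO, colour) of tested genes by GC content in percent (horizontal) and transcript length in bases (vertical), for cells of at least 20 genes; grey cells hold fewer. The highest median, 0.41, lies at 46 to 50% GC and 1500 to 2000 bases, and the lowest, -0.44, above 62% GC at 600 to 1000 bases.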

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

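The tests with limma-voom, protein-coding genes, no robust moderation and the GC and length correction were chosen after the data were seen. The count of called genes, 5178, ran from 3714 with a filter at 5 FPKM, which tests 5205 genes, to 5521 with limma-voom, within 1.5 times of it throughout; leaving out 1 library gave 4556 to 4774 genes, 78 to 88 genes at 2-fold and 6 lists each time. The 82 genes at 2-fold became 165 with a pseudocount of 0.1, 209 with limma-voom and 34 with the GC and length correction, of which 29 were among the 82; the cause was not tested. That correction kept 3111 of the 5178 called genes in the same direction and called 4236. The 6 called lists became 9 with no filter and 26 with fry, which does not compare a list with other genes. With camera and an estimated correlation the count was 0. That correlation was 0.00431 for the TCA cycle, below the fixed 0.01, so a higher correlation does not account for its lost call. It was 0.0165 for hypoxia, 0.0191 for pentose phosphate, 0.0254 for glycolysis, 0.0501 for autophagy and 0.651 for mitochondrially encoded mRNAs. With an estimated correlation camera also takes its degrees of freedom from the 6 libraries, and with a fixed one from the genes tested. A call lost with an estimated correlation therefore need not mean that the genes of a list are highly correlated. The cause of the changes in the count of lists was not tested further. Among lists that fry called, its direction was opposite to camera for ribosomal proteins (median -0.10), cell cycle (-0.06) and heat shock (-0.02), whose members went both ways. With the replicate block 4791 genes were called, 83 at 2-fold and 6 lists, and RMRP (adjusted p = 0.106) and MIR429 (0.0596) were not called by limma. Deviations from group means correlated weakly, at 0.11, -0.03 and 0.01 for numbers 1, 2 and 3. On principal component 2, with 10.7% of the variance, replicate 1 stood at 10.71 in DMSO and 6.81 in TBOEP. Replicates 2 and 3 stood at -4.09 and -6.99 in DMSO and at -5.01 and -1.43 in TBOEP. The labels do not say whether a number marks a shared day or passage, so whether the block applies is not known. Of 72 genes taken by the naming rule, 10 lost and 4 gained a call under some setting, and none of those called changed sign. The alternatives fixed beforehand for a table of deposited counts, or for one with a biotype column, were not run. In the 10 splits of 6 libraries the real one gave 5178 genes, 82 at 2-fold and 6 lists, and the highest other 2, 2 and 4; in each case 1 split, the real one, gave as many, but 10 splits are too few for a share under 0.05. Genes such as PCK1, at 2 reads or fewer in each library, were too low to compare at this depth.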

Other observations

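The tests in this part were chosen after the data were seen, apart from the gene lists, camera with either correlation and median centring, which were fixed before. Of 7 measured CCT chaperonin subunits, 7 rose and 0 fell, with a median log2 fold change of 0.74, from 0.14 for TCP1 to 1.57 for CCT3; with libraries centred on their medians 6 rose and 0 fell, and after the GC and length correction 6 rose, 1 fell and the median was 0.44. Of 16 measured subunits of the 19S proteasome, 10 rose and 3 fell, from -0.47 for PSMC6 to 1.19 for PSMD7; 5 fell with libraries centred on their medians, and after the GC and length correction 8 rose, 4 fell and the median went from 0.37 to 0.15. Of 8 annexins, 6 rose and 0 fell, from -0.10 for ANXA1 to 1.66 for ANXA2; with libraries centred on their medians 1 fell, and after the GC and length correction 5 rose, 1 fell and the median went from 0.52 to 0.33. Subunits of the CCT chaperonin, subunits of the 19S proteasome and members of the annexin family thus moved by unequal amounts. Of 12 subunits of the initiation factor EIF3, 6 rose and 3 fell, with a median of 0.11, from -0.50 for EIF3A to 1.18 for EIF3I on the log2 scale. With libraries centred on their medians 5 rose and 4 fell, and after the GC and length correction 6 rose, 3 fell and the median was 0.14.

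The first pattern weighed is the dependence of fold changes on GC content and length, which accounted for 34.2% of their variance across genes, against 13.2 to 24.9% in the other 9 splits of the libraries. A difference in depth is argued against, since 2 of the 3 TBOEP libraries lay inside the depth range of the DMSO libraries. Removing the trend kept 60.1% of called genes and 35.4% of the 2-fold calls, so GC or length bias may account for part of either, and a real change shared by genes of like GC content would be removed too. A difference in library preparation or RNA quality between the groups cannot be told apart from the treatment: within groups the trend was weak, with correlations of at most 0.12 in size between a library's deviation from its group mean and the fitted trend, and the labels do not assign the 2 kits to libraries. A response of the cells to TBOEP stays open as well, untested.

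The second pattern is that pseudogenes moved with their parent genes. Across 278 tested pseudogenes with a tested parent, Pearson's r of the log2 fold changes was 0.63 and Spearman's rho 0.63 (permutation p = 1e-04, the smallest that 10000 resamples can give; genes are not independent replicates). Of 88 pairs with both called, 79 went the same way. Reads shared between a gene and its pseudogenes are a candidate explanation, and no biological explanation was tested. Pairs of like sequence may also share the trend of fold changes with GC content and length. The pairs were not compared on values corrected for that trend, so it stays open too.

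The third pattern is the set of called gene lists. As their whole cause, the GC or length bias that the fitted surface removes is argued against for the 5 lists still called after the correction. These were hypoxia, mitochondrially encoded mRNAs, glycolysis, autophagy and the TCA cycle. A bias that the surface misses is not excluded. The correction also called the YAP and TEAD targets and the ribosomal proteins, which were not called before it. For the pentose phosphate and nucleotide list the median went from 0.22 to 0.07 and the adjusted p to 0.134 (camera, Benjamini-Hochberg), so the bias may account for it and stays open. Over all alternatives taken singly, fry among them, its adjusted p ran from 1.09e-04 to 0.422. Camera with both the correction and an estimated correlation gave 0.474. None of the 6 was called with an estimated correlation, before or after the correction, and a response to TBOEP was not tested apart from a preparation difference between the groups.

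In 32 tested genes with at least 100 reads, libraries of 1 group differed at least 5-fold on FPKM + 1. Of these, 11 had an absolute log2 fold change of 1 or more, and 0 were called by limma. Picking genes by a wide spread within a group selects against calls. The 0 is therefore no test of whether jumps that fall between the groups were called. EEF1B2 stood at 3.32, 262 and 100 FPKM in TBOEP replicates 1 to 3, RPS2 at 147, 2.72 and 2.55 FPKM in DMSO replicates 1 to 3, and CUTA at 49.9, 60 and 1.77 FPKM in the latter.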
